A study of Oryza sativa with 18 samples.

How the data were processed

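The series holds 18 strand-specific libraries of Nipponbare rice, 9 of m6A immunoprecipitates and 9 of input RNA, with 3 of each from panicles at booting, panicles at flowering and flag leaves at flowering. Per the labels the plants were grown in the field, and organs were collected at about 3 PM, panicles on 3 August (booting) and 14 August (flowering). No day is given for the flag leaves. Poly(A) RNA was cut into fragments of about 100 nt, of which a part was kept as input and the rest was enriched with an antibody against m6A. Stage and collection day of the panicles cannot be separated, and whether leaves and flowering panicles were collected on the same day is not labelled. Nothing in the labels says that libraries labelled as replicates came from separate plants or plots, so the p-values measure only the spread between samples labelled as replicates.

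Per the labels, the authors used cutadapt, HISAT2, StringTie, HOMER and ChIPseeker; their versions, the peak caller, the genome build and the strand setting of the quantification are not given in the sources used here. The deposited expression table gives FPKM for 38663 genes in the 9 input libraries. The deposited peak files give 1 list for each group, made from its 3 immunoprecipitates and 3 inputs, without values for single replicates. Per the file headers each peak has the base-10 logarithms of a p-value and an FDR, a score and a fold of immunoprecipitate over input. The score was read as the p-value itself, since it equals 10 to the power of the listed logarithm within rounding. The p-values are those the authors deposited and were used only to rank peaks within a list. The ratio of immunoprecipitate to input (fold) is deposited by the authors and was compared only within a list. The authors' position classes (5' UTR, exon, 3' UTR) were taken as listed.

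The depth of the inputs was read from the smallest steps of FPKM, which gave 29.1 to 33.1 M fragments per library. Of 1715 low values of 575 single-exon genes, 32.07% were whole fragment counts within 0.1, against 20% by chance, so whole reads were not recovered and tests of counts were not used. FPKM sums per library ran from 504583 to 569592. Between replicates of a group the variance was 2.44 to 8.15 times that of counting noise, so none duplicated another of its group. These values rest on approximate fragment counts of single-exon genes. Flag leaf replicate 3 gave 8.15 and 7.61 with replicates 1 and 2, against 2.44 between those. The median SD of log2 values within a group was 0.111 in booting panicles, 0.123 in flowering panicles and 0.0738 in flag leaves, and Pearson correlations between replicates were 0.9875 to 0.9956. The 10 most abundant genes took 2.89 to 3.31% of FPKM in booting panicles, 4.21 to 4.79% in flowering panicles and 12.5 to 13.1% in flag leaves. Replicates of the same number in different groups were not treated as pairs: residuals of same-number libraries correlated at -0.189 to 0.118, with 2 of 9 over 0.1.

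Expression was compared as log2(FPKM + 1) for genes with FPKM of at least 1 in 3 or more libraries (23355 genes), in limma 3.58.1 under R 4.3.3 with a trend in the prior variance. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. Comparisons were flowering against booting panicles and flowering panicles against flag leaves as main ones, and booting panicles against flag leaves in addition. The comparisons against the leaf share its 3 libraries, so overlaps between them are not reported. Lists of genes were fixed from descriptions and symbols before the data were examined, as were the comparisons, thresholds and all alternatives except those named in the closing section as chosen later. Of 16 lists, 15 were tested. The list of plastid and mitochondrial genomes held 1 member, an uncharacterized gene linked to the symbol PSAG (LOC_Os05g05600). By its locus name this gene lies on nuclear chromosome 5, so the list held no transcript of an organelle genome. The gene's log2 change was 2.32 for flowering against booting panicles and -3.31 for booting panicles against flag leaves. Against flag leaves its change in flowering panicles was -0.99, not called. It was called with a pseudocount of 0.1 (-1.001), equal library sums (-1.07), quantile normalization (-1.17) and without flowering panicle replicate 1 (-1.02). Lists were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation and with fry as alternatives, and adjusted over the 15 lists. No call of camera held with an estimated correlation. The named genes are the 10 called genes with the largest increase and the 10 with the largest decrease (3 each way between booting panicles and flag leaves) that had a symbol or an informative description, a mean of at least 20 FPKM in the higher group and all 3 libraries of one group above those of the other. To these were added up to 4 members of each list with the smallest adjusted p, all members of the m6A list, and for each peak list 5 genes with the lowest listed p-value, ties taken by fold. Symbols were linked to 3731 genes.

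The gene of each peak, and with it the strand, was taken as the authors list it. Peaks of different lists were joined to each other by that strand and exon block with bedtools 2.31.1 (overlap of 1 bp, or 50% reciprocal). Peaks listed again with the same coordinates were dropped (2, 3 and 5 in booting panicles, flowering panicles and flag leaves). Peaks with an FDR over 0.05 numbered 1046, 1040 and 1080 and were kept, since they are part of the authors' lists. Shares have exact 95% binomial intervals, which cover counting error only. Shares of list members with a peak were compared with other expressed genes by Fisher's exact test, and levels and changes by 100000 permutations across genes, for which 1e-05 is the smallest p possible. Genes are not independent replicates, so these p-values describe the gene sets of 1 list and not the spread between plants. Lists matched on expression (genes within 100 ranks) or on expression and genomic span (the 50 nearest genes) were drawn 10000 times.

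The expression test was checked on simulated data with the means and spreads of these genes, in which 200 genes were changed in flowering panicles alone. It found 93% of the genes changed 3-fold and 100% of those changed 8-fold against booting panicles, and 91% and 100% against flag leaves, with 0 false calls; between booting panicles and flag leaves, where nothing was changed, 0 genes were called. With core histones shifted between stages, that list was called and 0 of the 14 others were. Simulated genes varied independently of each other, so this check does not cover list calls among correlated genes. The 200 changed genes were drawn above a minimum mean level, so recovery of weakly expressed genes was not checked. In each of the 3 comparisons, 1 of the 10 splits of the 6 libraries into groups of 3, the true one, gave as many called genes as reported. Alternatives were pseudocounts of 0.1 and 5, equal library sums, quantile normalization, leaving out each library in turn, a term for replicate number, the stronger 50% of peaks by p-value, reciprocal overlap, a minimum of 5 FPKM and matching. A search for sequence motifs in peaks and a recount on another annotation were not run, as no genome sequence was used here. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots drawn with matplotlib 3.10.9.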

Results

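Input RNA and m6A peaks of Nipponbare rice were compared between panicles at booting, panicles at flowering and flag leaves at flowering. Expression levels are FPKM, given as mean ± SD (SD, n = 3 input libraries per group), and changes are log2 differences of FPKM + 1 with the SE of limma. A gene was called at an adjusted p under 0.05 (limma, Benjamini-Hochberg over 23355 genes) and a log2 change of at least 1 either way. The largest changes are those among genes that met the rule for naming.

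From booting to flowering, the list test put pollen and photosynthesis genes higher in the panicle and histone and cell cycle genes lower, but none of its 10 calls held with an estimated correlation. The pollen list was mixed, with 46 members rising and 30 falling of 99. The largest increase was that of classical arabinogalactan protein 6 (LOC_Os06g17450), a cell surface glycoprotein known from pollen. It stood at 1907 ± 391 FPKM at flowering and 3.68 ± 0.599 at booting (log2 change 8.66, SE 0.24, adjusted p = 7.27e-10; chromosome 6, 10126748 to 10127412, plus strand). Expansin-B9 (LOC_Os10g40090), of the wall-loosening beta-expansins, rose from 7.72 ± 1.11 to 3349 ± 357 FPKM (8.59, SE 0.32, adjusted p = 5.75e-09). The largest decrease was that of proline-rich protein 2 (LOC_Os03g14130), from 341.8 ± 43.0 to 0.361 ± 0.157 FPKM (-7.97, SE 0.14, adjusted p = 1.34e-10; chromosome 3, 7675743 to 7677125, minus strand). Levels of this kind in the lower group are near those at which libraries held genes abundant in another group (medians of 0.25 to 0.298% in booting panicles and 0.299 to 0.315% in flowering panicles). Their origin is open, so the size and rank of the largest changes are uncertain. Of the 23355 genes tested, 7802 were called, 4226 of them higher and 3576 lower at flowering.

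The other genes with the largest increases were an anther-specific protein (LOC_Os05g46530, 2717 ± 206 against 6.84 ± 0.962 FPKM) and pollen-specific protein C13 (LOC_Os04g32680, 1804 ± 308 against 5.87 ± 1.23). They further included a gene described as nucleolar and coiled-body phosphoprotein (LOC_Os02g05670, log2 change 8.38), SRC2 (LOC_Os01g27190, 8.08), defensin J1-2 (LOC_Os04g11130, 7.98) and RIC7 (LOC_Os07g26480, 7.92), one of the effectors of ROP GTPases. Profilin-A, an actin-binding protein, rose under both of its loci (LOC_Os10g17660, 7.97, and LOC_Os10g17680, 7.82). Such copies can share reads, so their separate values are uncertain. Among the decreases were type III polyketide synthase A (LOC_Os10g34360, 0.887 ± 0.170 against 448 ± 199 FPKM, -7.79) and cytochrome P450 704B1 (LOC_Os03g07250, 0.487 ± 0.135 against 172 ± 68.9, -6.77), both known from the synthesis of sporopollenin, the polymer of the pollen wall. YY1 (LOC_Os09g35700, -7.21), an anther gene, acid phosphatase 1 (LOC_Os05g09704, -6.97), proline-rich protein DC2.15 (LOC_Os02g44320, -6.96), LIM1 (LOC_Os08g43290, -6.92) and a chorismate mutase (LOC_Os12g38900, -6.78) fell as well.

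**Figure D1:**
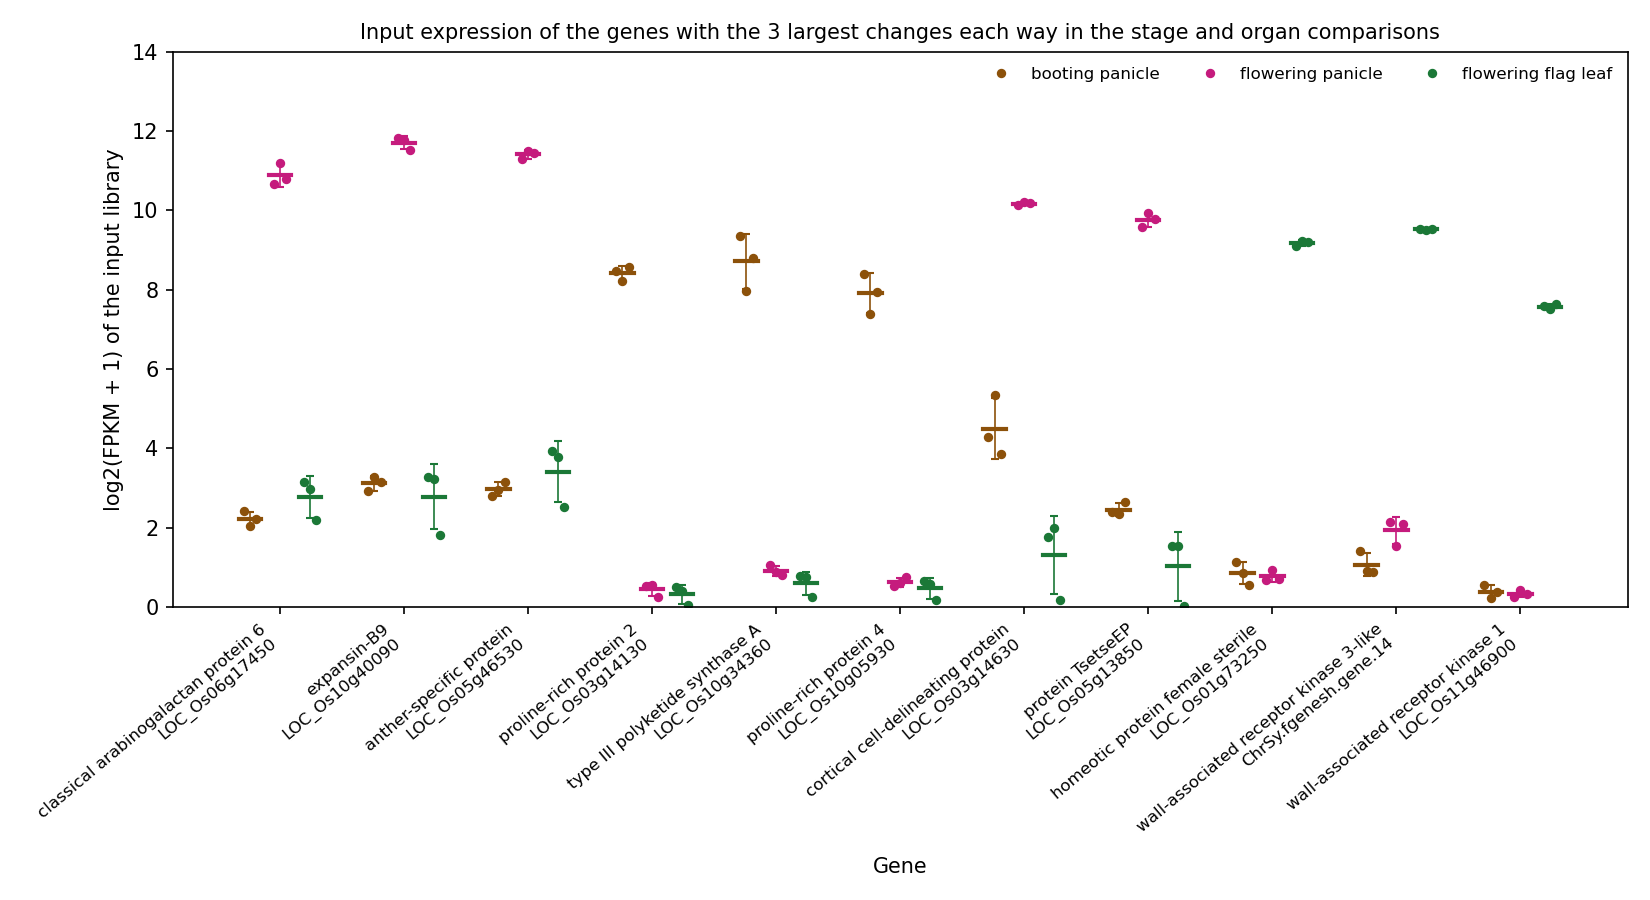
Input expression, as log2 of FPKM + 1 (vertical axis), of the genes with the 3 largest changes each way in both main comparisons (horizontal axis); points are libraries, horizontal lines the group means and vertical bars the SD of these log2 values (n = 3). Expansin-B9 stands at 3349 ± 357 FPKM in flowering panicles, against 7.72 ± 1.11 in booting panicles and 6.54 ± 3.47 in flag leaves.

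The set test camera called photosystem and Calvin cycle genes higher at flowering (adjusted p = 2.33e-08 and 0.00733), but not with an estimated correlation (adjusted p = 0.487 for each). Of 62 photosystem and antenna genes tested, 39 rose, none fell and 23 were not called (median log2 change 1.48); adjusted over the list alone, 38 rose. The photosystem II 22 kDa protein (LOC_Os04g59440), known for the dissipation of excess light, rose from 7.71 ± 0.748 to 377 ± 58.4 FPKM (5.43, SE 0.14), and the iron-sulfur subunit of the cytochrome b6-f complex (LOC_Os07g37030) from 27.2 ± 4.21 to 169 ± 4.87 FPKM (2.60, SE 0.10). Of 23 Calvin cycle and photorespiration genes, 11 rose, none fell and 12 were not called. Among the risers were RuBisCO activase (LOC_Os11g47970, 68.8 ± 11.8 to 1403 ± 122 FPKM, 4.34), a RuBisCO small subunit (LOC_Os12g17600, 4.87) and sedoheptulose-1,7-bisphosphatase (LOC_Os04g16680, 3.23). Of 9 senescence and chlorophyll breakdown genes, 6 rose and none fell, among them a pheophytinase (LOC_Os02g47620, 1.19 ± 0.183 to 11.3 ± 1.68 FPKM, 2.48), which removes the phytol chain in chlorophyll breakdown. Another was a senescence-induced receptor-like kinase (LOC_Os09g18594, 3.09). That list was called at adjusted p = 0.000576 (adjusted p = 0.451 with an estimated correlation).

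Camera called core histones and genes of DNA replication and the cell cycle lower at flowering (adjusted p = 5.14e-05 and 1.98e-05), but not with an estimated correlation (adjusted p = 0.487 for each). Of 34 core histone genes, 21 fell, none rose and 13 were not called (median -1.32). Histone H2A.5 (LOC_Os03g17100) fell from 364.5 ± 73.2 to 45.4 ± 3.90 FPKM (-2.96, SE 0.16), and H2A.6 (LOC_Os05g02300) from 77.6 ± 12.8 to 8.66 ± 0.947 FPKM (-3.02, SE 0.12). Of 58 genes of DNA replication and the cell cycle, 36 fell, none rose and 22 were not called (median -1.36). Cyclin-B1-3 (LOC_Os01g17402, 6.08 ± 0.298 to 0.911 ± 0.144 FPKM, -1.89) and the catalytic subunit of DNA polymerase delta (LOC_Os11g08330, 13.8 ± 0.936 to 4.47 ± 0.427, -1.44) were both called, but with a pseudocount of 5 their changes were -0.91 and -0.99, under the threshold. The fallers of that list included cyclin-dependent kinase inhibitor 3 (LOC_Os11g40030, -1.45, but -0.52 with a pseudocount of 5), of a family that restrains the cell cycle. Of 192 genes of cytosolic ribosomal proteins, 14 fell (22 without booting replicate 1 and 8 without booting replicate 3) and 4 rose, 2 without flowering replicate 3 (median -0.56, adjusted p = 4.46e-05, or adjusted p = 0.506 with an estimated correlation), with ubiquitin-60S ribosomal protein L40 (LOC_Os09g31031) falling from 31.2 ± 4.30 to 5.89 ± 0.416 FPKM.

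Of 99 genes of pollen maturation and tube growth, 46 rose, 30 fell and 23 were not called (median 0.81, adjusted p = 0.00947, or adjusted p = 0.498 with an estimated correlation). Pollen receptor-like kinase 3 (LOC_Os11g40550) rose from 0.105 ± 0.00923 to 45.2 ± 3.40 FPKM (5.38, SE 0.08), an exopolygalacturonase (LOC_Os01g33300), of a family that degrades pectin, by 5.95, and a pectinesterase (LOC_Os01g50810) by 6.97. Of 28 MADS-box factors 9 rose and none fell (adjusted p = 0.00988, or adjusted p = 0.487 with an estimated correlation), among them MADS13 (LOC_Os12g10540, 6.43 ± 0.466 to 39.1 ± 5.39 FPKM, 2.42), known for ovule identity, and AGL66 (LOC_Os06g11970, 3.28), of a pollen clade. Of 54 starch and sucrose genes 22 rose and 5 fell (median 0.52, adjusted p = 0.00561, or adjusted p = 0.487 with an estimated correlation). Risers included beta-fructofuranosidase 1 (LOC_Os04g45290, 1.11 ± 0.192 to 66.6 ± 10.6 FPKM), a sucrose-cleaving invertase, and a putative invertase inhibitor (LOC_Os02g01310, 5.81), while sucrose synthases 5 and 6 fell (LOC_Os04g24430, -3.18; LOC_Os02g58480, -3.81). Of 138 defence and pathogenesis related genes 56 rose and 25 fell (median 0.64, adjusted p = 0.00466, or adjusted p = 0.449 with an estimated correlation), with an acidic endochitinase among the risers (LOC_Os01g47070, 0.779 ± 0.209 to 168 ± 13.1 FPKM, 6.58).

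The other 5 lists were not called. Of 6 meiosis genes 2 fell: SPO11-4 (LOC_Os12g42760, 91.7 ± 6.67 to 22.5 ± 2.5 FPKM, -1.98) and the recombinase gene DMC1 (LOC_Os12g04980, -1.41, but -0.54 with a pseudocount of 5), with adjusted p = 0.192 for the list. The 5 tapetum genes split between the anther-specific protein, which rose, UDT1 (LOC_Os07g36460), which fell (-1.46, but -0.76 with a pseudocount of 5), and 3 without a call. The list's median was -0.52, its mean 1.07 and its test pointed down (adjusted p = 0.404). The polyketide synthase and cytochrome P450 of sporopollenin synthesis named above, both lower at flowering, were not linked to this list. It therefore says little about pollen wall genes as a whole. The secondary cell wall and lignin list went both ways, 13 up and 16 down of 61 (median -0.17, mean 0.04, adjusted p = 0.948). It takes in every gene described as a cellulose synthase A catalytic subunit or COBRA-like protein, so it is not confined to the secondary wall. COBRA-like protein 10 (LOC_Os06g47110) rose by 6.29 and cellulose synthase A5 (LOC_Os03g62090) fell from 96.9 ± 5.52 to 13.9 ± 0.451 FPKM (-2.72). Of 59 heat shock genes 15 rose and 7 fell (adjusted p = 0.884), with a chloroplastic small heat shock protein (LOC_Os10g07210) falling from 59.8 ± 7.99 to 0.424 ± 0.161 FPKM (-5.41). None of 8 genes on the list of m6A writers, erasers and readers was called (adjusted p = 0.325). The probable N6-adenosine-methyltransferase (LOC_Os02g45110), of the family of the writer enzyme, stood at 17.2 ± 0.315 FPKM at flowering and 22.6 ± 2.28 at booting (-0.36), Hakai (LOC_Os10g35190) differed by -0.55, and YTH domain family protein 2 (LOC_Os03g20180), of the reader family, by 0.74. The other members were an MT-A70 family gene (LOC_Os03g05420), Mettl10 (LOC_Os01g49250) and METTL21 proteins, which methylate protein lysines, and ALKBH2, a DNA demethylase. With such members, the list says little about m6A writers, erasers and readers as a whole.

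For every list other than the photosystem genes, the counts adjusted over the list alone equalled those over all genes, in each of the 3 comparisons. Equal library sums moved the median change of all genes from -0.09 to -0.20, so the changes are relative to the total of each library. The share of called genes that were higher at flowering was 54.2% as deposited and 49.1% after quantile normalization. With a pseudocount of 5, 4367 genes were called.

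**Figure D2:**
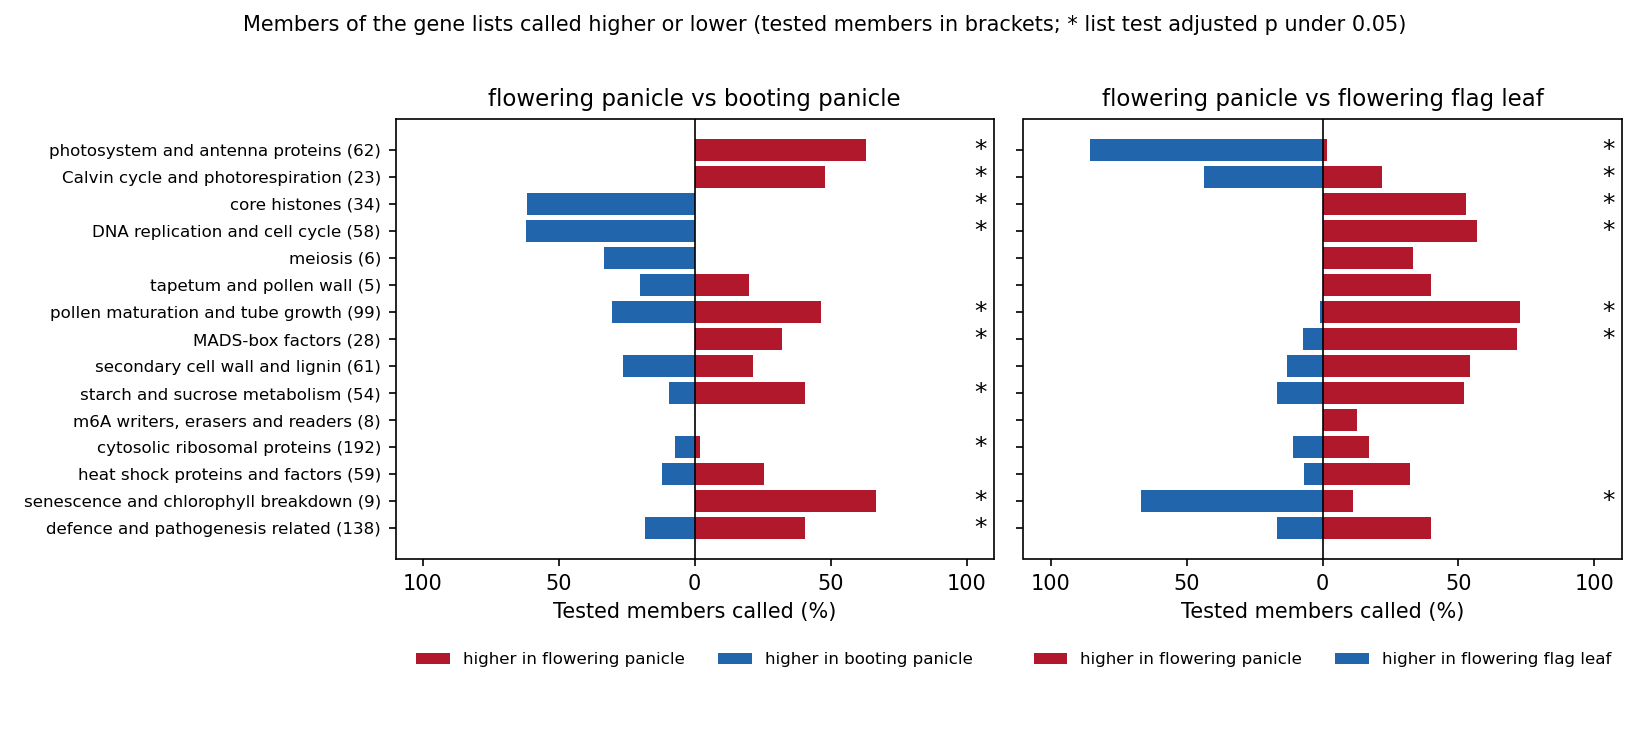
Percent of the tested members of each gene list (vertical axis, tested members in brackets) called higher in flowering panicles (to the right) or in the other group (to the left); stars mark lists with an adjusted p under 0.05 in camera at its preset correlation, none of which held with an estimated one. Photosystem genes lie to the right against booting panicles (39 of 62 higher) and to the left against flag leaves (53 of 62 lower).

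The list test put pollen and MADS-box genes higher in flowering panicles than in flag leaves and photosynthesis and senescence genes lower, but none of its 7 calls held with an estimated correlation. The MADS-box call was also lost with a pseudocount of 0.1 and the Calvin cycle call after quantile normalization. Expansin-B9 (LOC_Os10g40090) stood at 3349 ± 357 FPKM in flowering panicles and 6.54 ± 3.47 in flag leaves (8.93, SE 0.32, adjusted p = 2.77e-09). MADS8 (LOC_Os09g32948), a floral organ identity factor, stood at 254 ± 46.5 against 0.436 ± 0.166 FPKM (7.46, SE 0.14, adjusted p = 8.85e-11). RuBisCO activase (LOC_Os11g47970) stood at 1403 ± 122 FPKM in flowering panicles against 15600.0 ± 448 in flag leaves (-3.48, SE 0.15, adjusted p = 1.06e-08). Of the genes tested, 9930 were called, 7239 higher in flowering panicles and 2691 higher in flag leaves, and with a pseudocount of 5 the number was 5303.

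The largest increases over the leaf after expansin-B9 were a cortical cell-delineating protein (LOC_Os03g14630, 1150.0 ± 33.4 against 1.81 ± 1.49 FPKM, 8.87, SE 0.47) and TsetseEP (LOC_Os05g13850, 8.73; LOC_Os05g13830, 8.67). Profilin-A (LOC_Os10g17660, 8.52) and the pollen allergens Lol p 2-A (LOC_Os04g26220, 8.49, and LOC_Os06g45290, 8.35) and Phl p 2 (LOC_Os04g26230, 8.25) were also among the largest increases. Members of such pairs can share reads, so their split is uncertain. The gene described as homeotic protein female sterile (LOC_Os01g73250) had the largest decrease, 0.713 ± 0.174 against 577 ± 30.7 FPKM in the leaf (-8.40, SE 0.13, adjusted p = 8.16e-11). Wall-associated receptor kinases 3-like (ChrSy.fgenesh.gene.14, -7.59) and 1 (LOC_Os11g46900, -7.24), metallothionein 3B (LOC_Os05g11320, 29.3 ± 14.9 against 3668 ± 212 FPKM, -7.05), a thiol methyltransferase (LOC_Os03g62670, -6.94) and lipoxygenase 2.3 (LOC_Os02g10120, -6.87), of the pathway to jasmonate, came next. Beta-sesquiphellandrene synthase (LOC_Os08g04500, 9.31 ± 0.951 against 1023 ± 27.8 FPKM, -6.64) and terpene synthase 7 (LOC_Os03g22634, -5.83), ervatamin-B (LOC_Os06g38450, -5.67) and jacalin-related lectin 9 (LOC_Os04g26320, -5.53) were also higher in the leaf.

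Of 62 photosystem genes 53 were lower in flowering panicles and 1 was higher (median -1.65, adjusted p = 8.91e-16, or adjusted p = 0.385 with an estimated correlation). Among the lower ones, the cytochrome b6-f iron-sulfur subunit (LOC_Os07g37030) stood at 169 ± 4.87 against 879 ± 5.21 FPKM (-2.37). Photosystem I subunit VII (LOC_Os06g46436, -2.54) is listed under 3 near-identical nuclear copies of a plastid gene, so its value per copy is uncertain. Calvin cycle genes counted 10 lower and 5 higher of 23, with 3 higher without flowering panicle replicate 3 (median -0.87, adjusted p = 0.000443, or adjusted p = 0.475 with an estimated correlation); after quantile normalization the list was not called (adjusted p = 0.0714). Glycine dehydrogenase (LOC_Os01g51410) was lower (194 ± 31.1 against 2189 ± 176 FPKM, -3.50), while glycine cleavage H protein 2 (LOC_Os06g45670) was higher (32.1 ± 6.66 against 2.69 ± 0.271, 3.15). Of 9 senescence genes 6 were lower and 1 higher (adjusted p = 4.38e-05, or adjusted p = 0.385 with an estimated correlation), among the lower ones a pheophytinase (LOC_Os02g47620, 11.3 ± 1.68 against 57.1 ± 3.42 FPKM, -2.25).

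Of 99 pollen genes 72 were higher in flowering panicles and 1 was lower (median 2.46, adjusted p = 2.37e-08, or adjusted p = 0.385 with an estimated correlation), among them pollen receptor-like kinase 3 (LOC_Os11g40550, 45.2 ± 3.40 against 0.164 ± 0.0383 FPKM, 5.31). Flag leaf replicates 1, 2 and 3 held expansin-B9 at 8.69, 8.40 and 2.54 FPKM and the anther-specific protein (LOC_Os05g46530) at 14.2, 12.6 and 4.76 FPKM, so the leaf libraries were not equal. Replicate 3 was also the lowest for the cortical cell-delineating protein (2.37, 2.95 and 0.128 FPKM), TsetseEP (LOC_Os05g13850; 1.89, 1.89 and 0.0136) and proline-rich protein 2, which is abundant at booting (0.417, 0.326 and 0.0312). Whether panicle material or reads carried over between libraries lie behind these low levels is open, and the largest changes rest on them, over the leaf as between stages. Of 28 MADS-box factors 20 were higher and 2 lower (median 2.90, adjusted p = 0.0232, or adjusted p = 0.475 with an estimated correlation), a call lost with a pseudocount of 0.1 (adjusted p = 0.0543). MADS1 (LOC_Os03g11614, 718 ± 84.7 against 5.64 ± 0.915 FPKM, 6.76), MADS6 (LOC_Os02g45770, 6.02) and MADS17 (LOC_Os04g49150, 5.89), which act in floret and floral meristem identity, were among those higher. Histones (18 higher, none lower of 34, adjusted p = 0.0238) and replication and cell cycle genes (33 higher, none lower of 58, adjusted p = 0.0196) were higher in flowering panicles too, both with adjusted p = 0.784 with an estimated correlation. Examples were H2A variant 2 (LOC_Os10g28230, 11.6 ± 0.884 against 0.248 ± 0.140 FPKM, 3.34), the helicase subunit MCM5 (LOC_Os02g55410, 2.58) and cyclin-dependent kinase B2-1 (LOC_Os08g40170, 3.16).

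The other 8 lists were not called against the leaf, though they held genes with large differences. After quantile normalization secondary wall (adjusted p = 0.0307), starch and sucrose (adjusted p = 0.0461) and ribosomal genes (adjusted p = 0.00122) were called higher. Of 54 starch and sucrose genes 28 were higher and 9 lower (adjusted p = 0.41). ADP-glucose pyrophosphorylase, the enzyme that commits carbon to starch, was higher in its large (LOC_Os05g50380, 352 ± 30.5 against 7.15 ± 0.650 FPKM, 5.44) and small subunits (LOC_Os09g12660, 4.14), as was the sugar transporter SWEET15 (LOC_Os02g30910, 4.49). Of 61 genes on the secondary wall list, which is not confined to that wall, 33 were higher and 8 lower (adjusted p = 0.214). Cellulose synthase A1 (LOC_Os05g08370) stood at 88.7 ± 5.05 against 5.21 ± 0.572 FPKM (3.86). Of 192 ribosomal genes 33 were higher and 21 lower (adjusted p = 0.119), and of 59 heat shock genes 19 were higher and 4 lower (adjusted p = 0.41), the factor HsfA4d (LOC_Os05g45410, -2.55) among the lower. Meiosis genes (2 higher of 6, adjusted p = 0.098, but 4 without flowering panicle replicate 1 or flag leaf replicate 3) included SPO11-4 (LOC_Os12g42760, 3.34), and tapetum genes (2 higher of 5, adjusted p = 0.154) the anther-specific protein. On the list of m6A genes 1 of 8 was called, the lysine methyltransferase Mettl10 (LOC_Os01g49250, 1.14, but 0.67 after quantile normalization). Defence genes counted 55 higher and 23 lower of 138 with a median of 0.47 and a mean of 0.83, while the list's test pointed down (adjusted p = 0.902 for this and the m6A list). Pathogenesis-related PR-1 (LOC_Os05g51680, 70.5 ± 8.07 against 0.239 ± 0.134 FPKM, 5.85) was among the higher ones.

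Scaling moved the balance of this comparison. The median change of all genes was 0.44 as deposited, 0.37 with equal library sums and -0.12 after quantile normalization, so the changes are relative. The share of called genes that were higher in flowering panicles went from 72.9% to 47.1%, with 6891 genes called both ways. The medians of the m6A list (0.28 to -0.49) and of defence genes (0.47 to -0.09) turned negative with this shift of all genes. Relative to all genes they kept their sign (-0.16 and -0.36, 0.04 and 0.03).

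Booting panicles and flag leaves, which differ in stage as well as organ, gave 12622 called genes, 8492 higher in booting panicles and 4130 higher in flag leaves, or 7815 in all with a pseudocount of 5. MLP-like protein 423 (LOC_Os04g39150, 1922 ± 248 against 2.88 ± 1.94 FPKM, 9.10, SE 0.43), MFS18 (LOC_Os01g14850, 8.89) and non-specific lipid-transfer protein 1 (LOC_Os01g60740, 8.81) were highest over the leaf, and metallothionein 3B (LOC_Os05g11320, 5.81 ± 0.904 against 3668 ± 212, -9.08, SE 0.31) furthest below it. Photosystem genes were lower in booting panicles (59 of 62, none higher; adjusted p = 3.49e-19), as were Calvin cycle genes (14 lower, 5 higher of 23, adjusted p = 0.000169) and senescence genes (8 lower of 9, adjusted p = 1.47e-05). These had adjusted p = 0.394, 0.424 and 0.384 with an estimated correlation. Histones (27 higher of 34), replication and cell cycle genes (40 higher of 58, adjusted p = 0.000256 for both) and ribosomal genes (128 higher, 26 lower of 192, adjusted p = 0.00458) were higher, each with adjusted p = 0.638 with an estimated correlation. Histone H2A.5 (LOC_Os03g17100) stood at 364.5 ± 73.2 against 5.87 ± 1.25 FPKM (5.73) and MCM3 (LOC_Os05g39850) at 28.7 ± 3.57 against 0.0794 ± 0.0357 (4.78).

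Defence genes were called lower by the list test in that comparison (adjusted p = 0.043, or adjusted p = 0.394 with an estimated correlation), although 49 members were higher and 46 lower of 138 and the median and mean were both 0.01. That call was lost after quantile normalization (adjusted p = 0.178), with a pseudocount of 0.1 (0.0519) and without booting replicate 3 (adjusted p = 0.0509). Acidic beta-glucanase (LOC_Os01g71340, 0.551 ± 0.0625 against 62.8 ± 7.21 FPKM, -5.36) and chitinase-like protein 1 (LOC_Os09g32080, 102 ± 9.59 against 1.64 ± 0.0283, 5.28) went opposite ways. Of the lists not called, pollen genes counted 46 higher and 6 lower of 99 (adjusted p = 0.0577), and meiosis genes 5 higher of 6 (adjusted p = 0.0562). After quantile normalization both were called (adjusted p = 0.0459 each), as they were without booting replicate 2 (adjusted p = 0.0467 and 0.0489). Pollen genes were also called without flag leaf replicates 1 or 2 (adjusted p = 0.0432 and 0.038). MADS-box factors counted 15 higher and 5 lower of 28, tapetum genes 3 higher of 5, starch and sucrose genes 23 higher and 17 lower of 54, and heat shock genes 29 higher and 7 lower of 59 (adjusted p = 0.289 for these 4). The starch list's median was 0.31 although its test pointed down. The secondary wall list, which is not confined to that wall, counted 31 higher and 13 lower of 61 (adjusted p = 0.522). Cellulose synthase A5 (LOC_Os03g62090, 96.9 ± 5.52 against 0.920 ± 0.0758 FPKM, 5.67) and cinnamoyl-CoA reductase 1 (LOC_Os09g31514, 0.386 ± 0.0813 against 104 ± 8.79, -6.25) went opposite ways. Of the m6A list 2 of 8 were higher (adjusted p = 0.491), the MT-A70 family gene (LOC_Os03g05420, 1.06, but 0.56 after quantile normalization) and Mettl10 (LOC_Os01g49250, 1.80). Quantile normalization moved the median change of all genes from 0.51 to 0.00057 and the share of called genes higher in booting panicles from 67.3% to 50.6%. The median of the m6A list went from 0.43 to -0.20 with this shift, and relative to all genes was -0.08 before and -0.20 after.

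The deposited m6A peaks lay mostly at the 3' ends of genes in all 3 groups. The lists held 19081 peaks in 16489 genes for booting panicles, 19499 in 16709 for flowering panicles and 19544 in 16665 for flag leaves. Of these peaks the authors placed 79.7% (95% interval 79.1 to 80.2), 78.5% (77.9 to 79.1) and 79.2% (78.7 to 79.8) in 3' UTRs. They placed 5.22%, 5.27% and 5.32% in 5' UTRs and 15.1%, 16.2% and 15.4% in exons. The 3' edge of the peak lay within 100 bp of the gene's 3' end for 77.4%, 73.9% and 76.8%, and the median exonic length was 407, 390 and 420.0 bp. Most genes with a peak had 1 (87.5%, 87.1% and 86.8%).

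The named peaks of booting panicles all lay in 3' UTRs, among them that of the homolog of TSR1 (LOC_Os11g19250, fold 70.8, chromosome 11, 11021585 to 11023298, plus strand), a pre-rRNA processing protein. Others were in the alpha subunit of methylcrotonoyl-CoA carboxylase (LOC_Os12g41250, fold 66.0) and starch branching enzyme 3 (LOC_Os06g26234, fold 50.9). In flowering panicles ubiquitin carboxyl-terminal hydrolase 17 (LOC_Os08g37350) carried a 5' UTR peak of fold 111.0 (chromosome 8, 23600563 to 23601132, minus strand), and anaphase-promoting complex subunit 5 (LOC_Os12g43120) a 3' UTR peak of fold 50.4. In flag leaves the 3' UTR peaks of a glycine-tRNA ligase (LOC_Os06g01400, fold 40.7), Mediator subunit 31 (LOC_Os07g07020, fold 39.7) and autophagy protein 5 (LOC_Os02g02570, fold 38.8) were among those named. Pollen-specific protein C13 (LOC_Os04g32680), abundant at flowering, had a 5' UTR peak in all 3 lists, and MADS1 (LOC_Os03g11614) a 3' UTR peak in all 3. The booting level of C13 is near that at which booting libraries held genes abundant at flowering (medians of 0.25 to 0.298% of the flowering level). Whether its booting peak comes from RNA of booting panicles is therefore open. Flag leaf replicates 1, 2 and 3 held genes abundant at flowering at medians of 0.254%, 0.287% and 0.0473%. The origin of the leaf peaks of C13 and MADS1 was not tested either. Folds were not compared between lists, since each group has 1 list without replicates.

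Most peaks recurred between groups. Of booting peaks 88.5% overlapped a flowering panicle peak by at least 1 bp on the same strand, and 86.9% the other way round. Of flowering panicle peaks 85.7% overlapped a flag leaf peak, and 84.6% the other way round. Of 15281 genes with FPKM of at least 1 in every group, 11395 (74.6%) had a peak in all 3 lists and 2621 (17.2%) in none. Of the others 109 had one in the booting list alone, 77 in the flowering panicle list alone and 513 in the flag leaf list alone. Peaks without overlap in either other list numbered 1482, 1404 and 2297 (booting, flowering panicle, flag leaf). Their genes had a median of 0.647, 0.563 and 1.49 FPKM, and 34.6%, 32.7% and 48.3% of these peaks were in 3' UTRs. For peaks that overlapped another list these values were 11.1, 9.91 and 8.04 FPKM and 83.5%, 82.1% and 83.4%. Of the peaks of one list alone 35.4%, 35.7% and 23.5% had an FDR over 0.05, against 2.96%, 2.98% and 3.13% of the others, so many were weak calls. Since a list has no replicates, a peak absent from one list was not tested as a difference in methylation.

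Whether a gene had a peak went with its expression. Of expressed genes (FPKM of at least 1) 68.9%, 66.8% and 75.9% had a peak in booting panicles, flowering panicles and flag leaves, against 13.1%, 14.1% and 16% of the others. The share was 84.0%, 81.7% and 87.2% between 20 and 50 FPKM but 42.0% (21 of 50, interval 28.2 to 56.8), 17.8% (16 of 90, interval 10.5 to 27.3) and 52.0% (51 of 98, interval 41.7 to 62.2) from 500 FPKM. Among expressed genes, those with a peak had a mean log2 expression higher by 0.94, 0.67 and 0.72 (permutation across genes, p = 1e-05 each, the smallest it can give). With FPKM of at least 5 the differences were 0.22, -0.12 (permutation p = 1e-05) and -0.01 (permutation p = 0.849), so the sign turned in flowering panicles. They were 1.51, 1.32 and 1.45 when the stronger 50% of peaks by p-value were counted.

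**Figure D3:**
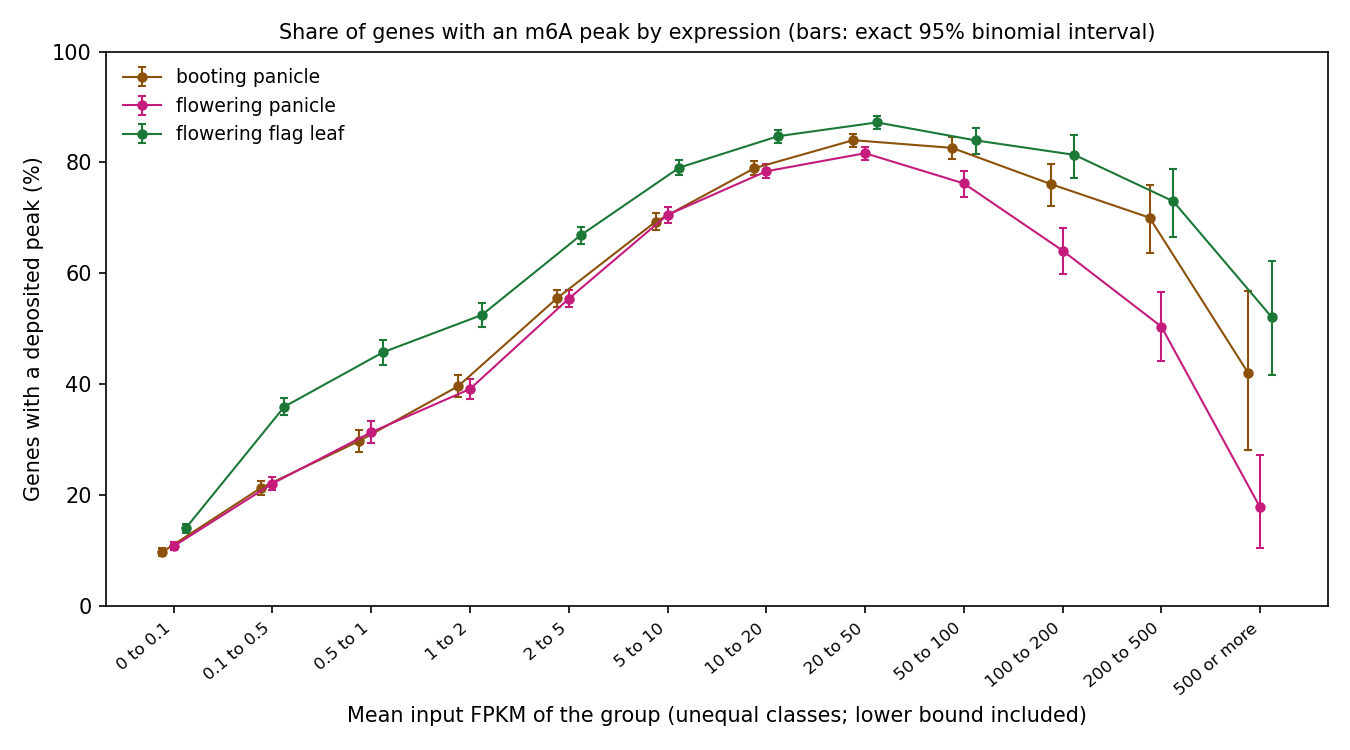
Percent of genes with a deposited m6A peak (vertical axis) by mean input FPKM of the group (horizontal axis, classes of unequal width) for booting panicles, flowering panicles and flag leaves; points are shares and bars exact 95% binomial intervals, which cover counting error only. From 500 FPKM the shares are 42.0%, 17.8% and 52.0%, against 84.0%, 81.7% and 87.2% between 20 and 50 FPKM.

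Photosystem, histone, pollen and defence genes had a peak less often than other expressed genes in every group. Against lists matched on expression and span, however, histones (percentiles 27.01, 14.84 and 27.48 in booting panicles, flowering panicles and flag leaves), photosystem genes of the panicles (8.39 and 12.05) and pollen genes of the leaf (4.38) lay inside the central 95%. Of expressed photosystem genes 12 of 45, 12 of 52 and 16 of 65 had one in booting panicles, flowering panicles and flag leaves (26.7%, 23.1% and 24.6%, against 69.0%, 66.9% and 76.1% of other genes; Fisher's exact test, adjusted p = 3.74e-08, 8.78e-10 and 1.73e-16). Histones counted 11 of 34, 9 of 34 and 11 of 23 (adjusted p = 6.11e-05, 1.19e-05 and 0.0134). Pollen genes counted 31 of 66, 27 of 88 and 15 of 30 (0.000893, 6.58e-11 and 0.00638) and defence genes 40 of 91, 39 of 118 and 33 of 81 (4.9e-06, 1.52e-12 and 1.3e-10). Genes on the secondary wall list had a peak less often in booting panicles (24 of 53, adjusted p = 0.00156). Ribosomal protein genes had a peak more often in booting (150 of 165, 90.9%, adjusted p = 1.3e-10) and flowering panicles (151 of 173, 87.3%, 5.69e-09), with 80.1% in flag leaves (153 of 191, adjusted p = 0.249). That leaf share lay at the 29.47 percentile of lists matched on expression but above the lists matched on expression and span (median 64.92%), and with the stronger 50% of peaks it was 74.4% against 52.6% (adjusted p = 8.98e-09). MADS-box genes had a peak more often in booting panicles (23 of 24, adjusted p = 0.00847). That call was lost with the stronger 50% of peaks (adjusted p = 0.218), and the share lay at the 94.21 percentile when matched on expression and span, as these genes are long (median 6430 against 3470 bp). These 16 calls, 13 lower and 3 higher, were made among 42 tests with the Benjamini-Hochberg method. Against lists matched on expression there were 23, 14 lower and 9 higher, the 16 among them. All 8 genes of the m6A list had a peak in both panicle groups and 6 of 7 in flag leaves. Of all expressed genes, 68.9%, 66.8% and 75.9% had one in booting panicles, flowering panicles and flag leaves. The m6A list was not among the 16 calls.

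For genes with a peak at one stage alone, the sign of the difference in expression change rested on which peaks were counted. Between stages, 479 genes had a peak in the flowering panicle list and not in the booting list, and 499 the reverse, with FPKM of at least 1 in both groups. Their mean changes from booting to flowering were -0.06 and 0.17, a difference of -0.23 (permutation across genes, p = 0.0183). This was -0.49 (permutation p = 0.00026) with FPKM of at least 5, -0.27 (p = 0.0101) when matched on expression and -0.20 (p = 0.062) with a pseudocount of 0.1. It was -0.17 (permutation p = 0.0846) with peaks of FDR of 0.05 or less and 1.92 (permutation p = 1e-05) when peaks of the stronger 50% by p-value were used (684 and 538 genes). With the stronger 50%, here and between organs, a gene with only a weaker peak in the other list counted as without one there. Between flowering panicles and flag leaves, 183 and 861 genes gave a difference of 0.18 (permutation p = 0.141). It was 0.37 (permutation p = 0.00569) with peaks of FDR of 0.05 or less, 0.26 (p = 0.0615) with a pseudocount of 0.1, 0.18 (p = 0.238) when matched on expression, -0.17 (p = 0.375) with FPKM of at least 5 and 2.22 (p = 1e-05; 596 and 1035 genes) with the stronger 50% of peaks.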

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

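The alternative that kept only peaks with FDR of 0.05 or less was chosen after results were seen; all other alternatives were planned. No named gene that was called in the main test changed direction. Changes of sign among named genes without a call were not counted. Of the values of named genes, 2101 kept their side of the threshold under the other settings, 26 became weaker and 11 stronger; when 1 library was left out, 1433 kept it, 2 became weaker and 5 stronger. Counts of called genes ran from 7608 to 7946, 9799 to 10076 and 12544 to 12754 without 1 library (flowering against booting panicles, flowering panicles against flag leaves, booting panicles against flag leaves), and a term for replicate number gave 7807, 9934 and 12628 with the same numbers of lists called. A pseudocount of 5 gave 4367, 5303 and 7815 called genes; it shrinks changes of weakly expressed genes by construction. Of the lists, 10, 7 and 7 were called; 0, 0 and 0 with an estimated correlation, and 13, 15 and 14 with fry, which does not compare a list with other genes. Fry did not call defence genes between booting panicles and flag leaves (adjusted p = 0.0551, direction up), where the main test called them lower. Their median was 0.01 against 0.51 for all genes, so they lie low against other genes and near 0 by themselves. Depth, at 29.1 to 33.1 M fragments per input, limits genes under 1 FPKM; depth of the immunoprecipitates was not analysed here.

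Values for peaks follow in the order booting panicles, flowering panicles and flag leaves. The stronger 50% of peaks by p-value numbered 9549, 9752 and 9780 peaks (ties at the cut are kept). Of these, 96.3%, 96.0% and 95.9% lay in 3' UTRs, 2.28%, 2.52% and 2.45% in 5' UTRs and 1.46%, 1.5% and 1.68% in exons; with FDR of 0.05 or less, 82.8%, 81.8% and 81.8% lay in 3' UTRs and 12.1%, 13% and 13.2% in exons. The share of booting peaks with a flowering panicle peak was 76.9% with reciprocal overlap of 50%, 93.2% for the stronger 50% and 90.7% with FDR of 0.05 or less; the other way round it was 75.3%, 91.3% and 88.8%. For flowering panicle peaks with a flag leaf peak these values were 72.7%, 88.0% and 86.8%, and the other way round 73.4%, 87.7% and 86.1%. Genes with a peak in all 3 lists made up 84.4% of those with FPKM of 5 or more, and 49.4% when the stronger 50% of peaks were counted.

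The higher expression of genes with a peak turned to -0.12 (permutation p = 1e-05) and -0.00637 (permutation p = 0.849) in flowering panicles and flag leaves with FPKM of 5 or more. With the stronger 50% of peaks the differences were larger, at 1.51, 1.32 and 1.45. The stage difference, -0.23 in the main test, was -0.49 (permutation p = 0.00026) with FPKM of 5 or more and -0.27 (p = 0.0101) when matched on expression. It was -0.20 (permutation p = 0.062) with a pseudocount of 0.1, -0.17 (p = 0.0846) with FDR of 0.05 or less and 1.92 (p = 1e-05) with the stronger 50% of peaks. The organ difference, 0.18 in the main test, was 0.26 (permutation p = 0.0615) with a pseudocount of 0.1, 0.18 (p = 0.238) when matched on expression and -0.17 (p = 0.375) with FPKM of 5 or more. It was 0.37 (permutation p = 0.00569) with FDR of 0.05 or less and 2.22 (p = 1e-05) with the stronger 50%. Lists with a peak share apart from other genes numbered 16 in the main test, 17 with the stronger 50% and 16 with FDR of 0.05 or less. Against lists matched on expression 23 lay outside the central 95%, 14 lower and 9 higher, and the 16 were among them. Apart from what the test of peak strength below shows, the cause of these changes was not tested.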

Other observations

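The pathway tests (762 for expression, 373 for peaks), the genes named from them, the test of expression level against the low peak shares, the division of the tests of short genes and gene copies by list and organ, the run without 100 abundant genes, the low levels per library, the count of numbered family members and the counts of splits were chosen after results were seen. Diterpenoid biosynthesis, the KEGG pathway that holds gibberellins and the phytoalexins of rice, was higher at flowering than at booting: 45 of its 74 tested genes rose, 60.8% against 18.9% of other genes (hypergeometric test, adjusted p = 6.45e-13, median log2 change 1.62). The pathway tests take genes as independent, and no correlation between genes was estimated for them. Genes of phytoalexin synthesis were among the risers. Ent-copalyl diphosphate synthase 2 (LOC_Os02g36210) stood at 37.1 FPKM at flowering and 0.147 at booting (5.04, SE 0.12, n = 3, adjusted p in limma = 2.76e-10). Ent-cassadiene synthase (LOC_Os02g36140) stood at 6.30 and 0.0191 FPKM, syn-pimaradiene synthase (LOC_Os04g10060) at 9.98 and 0.0186 FPKM, and a pimaradiene oxidase (LOC_Os04g09920) at 10.3 and 0.0601 FPKM. The synthases named first lie on chromosome 2 and the others on chromosome 4, where clusters of phytoalexin genes are known. Of gibberellin metabolism, which was not tested apart, a gene of activation rose (gibberellin 3-beta-dioxygenase, LOC_Os05g08540, 4.45), as did one of inactivation (gibberellin 2-beta-dioxygenase 2, LOC_Os05g06670; 200.8 against 3.05 FPKM, 5.91, SE 0.45). Against flag leaves, 39 of 74 genes of this pathway were higher in flowering panicles (adjusted p = 0.00206).

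Of 91 tested genes of tryptophan metabolism, 39 were higher at flowering (adjusted p = 7.35e-06), among them a catalase (LOC_Os02g02400, 618 against 16.9 FPKM, 5.11) and YUCCA2 (LOC_Os01g12490; 21.4 against 0.292 FPKM, 4.08), of the enzymes that make auxin. Genes of plant hormone signal transduction fell more often than other genes, 174 of 752 (23.1% against 13.8%, hypergeometric test, adjusted p = 2.13e-09). Their median log2 change was -0.02. The fallers included XTH32 (LOC_Os03g01800; 0.410 against 104 FPKM, -6.18), bHLH137 (LOC_Os08g42470, -5.85), auxin response factor 11 (LOC_Os04g56850, -3.64) and the receptor kinase ERECTA (LOC_Os06g10230; 4.36 against 53.4 FPKM, -3.34). Against flag leaves, genes of phenylpropanoid biosynthesis (141 of 269, adjusted p = 3.4e-11) and oxidative phosphorylation (125 of 262, adjusted p = 8.94e-07) were higher in flowering panicles more often than other genes. Genes of the spliceosome had a peak more often than other expressed genes with a pathway. They counted 354 of 429 in booting panicles, 368 of 440 in flowering panicles and 358 of 419 in flag leaves. These shares were 82.5%, 83.6% and 85.4%, against 72.4%, 69.7% and 77.6% (Fisher's exact test, adjusted p = 3.07e-05, 2.13e-09 and 0.000625). Genes of anthocyanin biosynthesis had one less often (1 of 16, 2 of 25 and 5 of 20, against 72.99%, 70.46% and 78.15% of others). Fisher's exact test gave adjusted p = 7.63e-07, 4.03e-09 and 1.13e-05 for these. Neither pathway was compared with genes matched on expression or span. The most abundant transcripts of the flag leaf were RuBisCO activase (LOC_Os11g47970; 15600.0 FPKM) and metallothionein 3A (LOC_Os01g10400; 14160.0 ± 849 FPKM, SD, n = 3), without a peak, and the photosystem II 10 kDa polypeptide (LOC_Os08g10020; 9602 ± 134 FPKM), with one.

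Genes with a mean of at least 100 FPKM in one group and under 1% of that in both others were seen at low levels in the other libraries. The 169 such genes of flowering panicles had a median of 0.25%, 0.258% and 0.298% of their flowering level in booting panicle replicates 1, 2 and 3, and of 0.254%, 0.287% and 0.0473% in those of the flag leaf. For the 27 genes of booting panicles the medians were 0.299%, 0.315% and 0.312% in flowering panicles and 0.175%, 0.177% and 0.043% in flag leaves. For the 14 genes of flag leaves they were 0.201%, 0.141% and 0.14% in booting panicles and 0.377%, 0.243% and 0.381% in flowering panicles. Of the flag leaf libraries, replicate 3 was the lowest for 163 of the 169 and for 26 of the 27 genes. Whether these levels are expression, material of another organ or reads carried over between libraries is left open.

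Photosystem, histone, pollen and defence genes had a peak less often than other expressed genes. Expression level, as far as it was matched, does not account for this: among lists matched on expression, their shares lay at the 1.78 percentile at most. Short genes could account for the histones (lowest percentile 14.84 among lists matched on expression and span), the photosystem genes of the panicles (8.39) and the pollen genes of the leaf (4.38), which have shorter spans than other genes. Photosystem genes of the leaf (percentile 0.0), pollen genes of the panicles (0.205 at most) and defence genes (0.07 at most) lay below the central 95% of such lists. Whether the genes drawn for the most abundant members were as abundant was not checked. Peak shares depend on this, at 81.4% from 100 to 200 FPKM but 52.0% from 500 FPKM in flag leaves. In flowering panicles these shares were 64.1% and 17.8%. Short span is therefore not settled for these genes. Nor is expression level for the most abundant members of the lists, as genes within 100 ranks of them can be less abundant. Reads shared between gene copies stay open. Genes with a description of their own lay at the 0.075 percentile at most for photosystem, histone and defence genes, at 0.795 at most for pollen genes of the panicles and at 9.57 for those of the leaf (8 members). In booting panicles, however, 19 of 22 such histone genes and 28 of 33 such defence genes are numbered members of a family. A name of its own thus does not show a sequence of its own. Fewer photosystem genes are numbered members (14 of 34, 15 of 38 and 16 of 41 in booting panicles, flowering panicles and flag leaves). Lower methylation stays open as well, as it had no test of its own.

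More called genes were higher in flowering panicles than in flag leaves as deposited (72.9%), but not after quantile normalization (47.1%). A few genes that take much of the leaf's FPKM might lower all others: the 10 most abundant genes took 12.5 to 13.1% of it. Without the 10 most abundant genes of each library and with equal sums, however, the median change of all genes was still 0.29. Without 100 it was 0.24, against 0.37 with all genes and equal sums, so these abundant genes do not make the whole shift. A wider set of genes expressed in panicles stays open, as the difference between organs that the design names was not tested apart from scaling.

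Genes with a peak at flowering alone and at booting alone differed by -0.23 in their expression change when any peak was counted, but by 1.92 when the stronger 50% were. The latter sets take in genes that had a weaker peak at the other stage, so they are not genes with a peak at 1 stage alone. The strength of the peak p-value rose with FPKM across genes in each list (Spearman's rho 0.636, 0.644 and 0.715 for booting panicles, flowering panicles and flag leaves; genes are not independent replicates), while the fold did not do so to that degree (0.106, 0.043 and 0.088). A cut on p-value could therefore select the more expressed member of each pair of groups, which is consistent with the lowest rho of 0.636. Whether methylation and expression also change together was not tested, as each group has 1 peak list.

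Of the 10 ways to split the 6 libraries of each comparison into groups of 3, 1 gave as many called genes as the true groups, the true split itself. The highest number from any other was 1 gene for flowering against booting panicles and 0 for both comparisons with flag leaves. These other splits mix both groups, so the difference between the groups enters their spread and low counts were built in. With 10 splits this share cannot fall under 0.05, so a grouping by chance and the groups cannot be told apart by this count alone.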
